A study of Mus musculus with 13 samples.

How the data were processed

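The authors deposited a table of 24421 transcripts by 13 libraries, 20451 with protein-coding (NM) and 3970 with non-coding (NR) accessions. Per the submitters' processing notes reads were aligned with HISAT to mm9 and counted with HOMER, whose versions are not given in the sources used here. The deposited values are reads per gene scaled to 10000000 mapped reads. Every value was a whole number of reads to within 0.01, so reads were recovered from it. 1 read was worth 3.092 to 6.585. Reference files of another genome build were used only for transcript GC content and length, which matched 14779 of the 15060 tested genes (98.1%), and no coordinates were used.

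The design foresaw either counts or normalized values, and since the values are normalized the main test was limma 3.58.1 (R 4.3.3, statmod 1.5.0). It was run on log2(value + 1) with a mean for each of the 6 groups, over all 13 libraries, with moderated variances that follow expression and are robust to outlying genes. Genes with a value of at least 1 in at least 2 libraries were tested, 15060 in all. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 are called changed. SD, n and SE are given for libraries, and the SE is that of limma. A group with no read is compared with a floor of 3 reads over the group, and groups of 1 to 3 reads are given as a read ratio with a 95% interval, which covers counting error only. These folds and ratios use reads pooled over the libraries of a group, so they can differ from ratios of the printed means.

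The 11 comparisons, set before the data were examined, were 1 day after the first LPS, 4 weeks and 12 weeks each against no LPS, the second challenge at each interval against its own baseline and against the first challenge, the 2 interactions (second response minus first response), and 12 against 4 weeks without and with the second challenge. The labels do not give the age of the mice without LPS at harvest, so whether they match the 4 and 12 week groups in age is not known. They also do not say which mice received PBS and when. So whether the baseline mice at 4 and 12 weeks had a control injection at the second time point is not known, and each second response may hold the effect of an injection itself.

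The 25 gene lists were also written before the data were examined and hold 603 entries, of which 600 are in the table. Of inflammation and myeloid cells they are interferon response, NF-kB targets, LPS receptor and signalling components, C/EBP and STAT3 acute-phase genes, neutrophil and monocyte granule markers, myeloid progenitor genes, and macrophage markers. Of other lineages and stem cells they are erythroid markers, megakaryocyte and platelet genes, B cell and lymphoid progenitor markers, T and NK cell markers, LT-HSC identity genes, and multipotent progenitor genes. The rest are DNA replication and G1/S genes, G2/M and mitosis genes, immediate-early genes, MHC class I and class II antigen presentation, glycolysis, oxidative phosphorylation, cholesterol synthesis, cytosolic ribosomal protein, HSC ageing-associated genes, chromatin modifiers and gate genes. Some genes are in more than 1 list, such as Ccl5, Selp and Vwf. Lists were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists. The same test with a correlation estimated from the data is given beside it, and the rotation test fry mainly as counts of called lists among the alternatives. In the first response, where 2300 of all 15060 genes were called, the changed members of lists without a call were as follows: LPS receptor and signalling components (3 of 25 higher, 3 lower, adjusted p = 0.76), granule markers (2 of 23 lower, adjusted p = 0.76), B cell markers (0 of 11, adjusted p = 0.92), glycolysis genes (2 of 20 higher, 2 lower, adjusted p = 0.11), G2/M genes (2 of 27 lower, adjusted p = 0.92) and DNA replication genes (1 of 30 lower, adjusted p = 0.35). Without replicate 1 of the first response more of their members were called: 13 DNA replication genes lower, 2 LPS receptor genes higher and 8 lower, 7 glycolysis genes higher and 3 lower, 1 granule marker higher and 5 lower, and 1 G2/M gene higher and 6 lower.

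Named genes follow a rule. Outside the interactions, their values must not overlap between the libraries of the 2 groups compared. Taken are the 6 largest risen and 6 largest fallen called genes per comparison, with a mean above the median of those tested and a proper name. To these come up to 4 called members of each list with the smallest p, or 2 members as values where a list passed with no called member. Kit, Ly6a, Slamf1, Cd48, Flt3, Cebpb, Cebpd and Tlr4 were fixed for every comparison. The text names fewer and keeps the order. Near copies (Hbb-bt and Hbb-b2, Hba-a1 and Hba-a2, Csf2rb and Csf2rb2, and the H2, Gbp, Ifit and Ly6 families) may share reads.

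Alternatives set beforehand were pseudocounts of 0.1 and 5, no expression filter, at least 5 CPM in 2 libraries, median-of-ratios scaling, a replicate-number block, only the groups compared, a log2 change of at least 1, limma-voom on the recovered reads, and leaving out each library of the groups compared. Alternatives added after the data were seen were array weights of limma, thinning to 1096465 reads per library, removal of each library's trend on GC content and transcript length, replicate 1 of the first response alone, no library of the first response, and leaving out each library of the groups not compared. Where a group is left with 1 library, its spread is taken to be that of the other groups. Similarity of responses was computed over 8963 genes with a mean of at least 100, against 20 simulations without a response. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

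In a self-test reads were simulated from the means and depths of these libraries with 1 dispersion for all, and 100 genes were changed 2-fold and 100 4-fold. There limma recovered 57% and 99% for the first response and 43% and 98% for the second response at 4 weeks. It recovered 35% and 96% at 4 weeks against no LPS, and 8% and 84% for the interaction at 4 weeks, with 5, 10, 10 and 4 false calls. The simulated replicates do not hold the difference of replicate 1 from the others of the first response (chi-square per degree of freedom 33.99 and 30.18), so these rates are not those of the data.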

Results

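RNA was sequenced from long-term haematopoietic stem cells (LT-HSCs), the bone marrow cells that can sustain blood formation for life, of C57BL/6 mice given lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that is sensed by Tlr4. The cells were sorted as lineage-negative, Kit-positive and Sca-1-positive cells without Flt3 or CD48 and with CD150. The 13 libraries fall into 6 groups. Mice without LPS gave 2 libraries, mice 1 day after a first LPS injection gave 3, and mice 4 weeks or 12 weeks after it gave 2 each. Mice injected again after 4 weeks or 12 weeks, and sampled 1 day later, also gave 2 libraries each. The labels give an LPS dose of 125 µg for the injected groups and an age of 6 to 8 weeks for every library. Per the labels each library comes from 8000 cells of 3 to 8 pooled mice, but they do not say that the pools of a group were independent, so p-values measure the spread between these libraries, part of which may be technical. Between 1518582 and 3234584 reads were mapped per library and between 1096465 and 2308087 fell in genes. Values are reads per gene scaled to 10000000 mapped reads, given as mean ± SD over n libraries. At this depth 1 read is worth 3.092 to 6.585, and read ratios and lower bounds cover counting error only.

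The libraries without LPS and those 4 or 12 weeks after it lay together on the first principal component, which held 48.34% of the variance, and all libraries taken 1 day after LPS lay on its other side. The 3 libraries taken 1 day after the first LPS were of 2 kinds. Replicates 2 and 3 correlated at 0.9785 across genes, which are not independent replicates, while replicate 1 correlated with them at 0.7742 and 0.7854. The pairs within the other groups reached 0.9436 to 0.9697. In replicates 2 and 3, Rpl36, a ribosomal protein gene, stood at 3314 and 2821 against 165 to 338 in all other libraries. Gas5, a non-coding RNA that hosts small nucleolar RNAs, stood there at 105 and 114 against 1420 to 3210. Of 8963 expressed genes, replicate 1 lay beyond all other libraries by more than 1 log2 in 140 above and 618 below, and replicates 2 and 3 together did in 57 and 121. These counts are not alike, since a pair passes only where both of its libraries do. No other single library was counted in this way. Replicate 1 held more of some inflammatory transcripts. Cxcl10, an interferon-induced chemokine, was at 140400 there and at 13720 and 15390 in the other 2 replicates. Cd40, a costimulatory receptor, was at 1418 against 145 in both. These 4 genes were chosen after their values were seen. The gene counts, and the medians and called members of the lists, were therefore also computed without replicate 1 and with replicate 1 alone in each comparison that uses these 3 libraries.

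**Figure D1:**
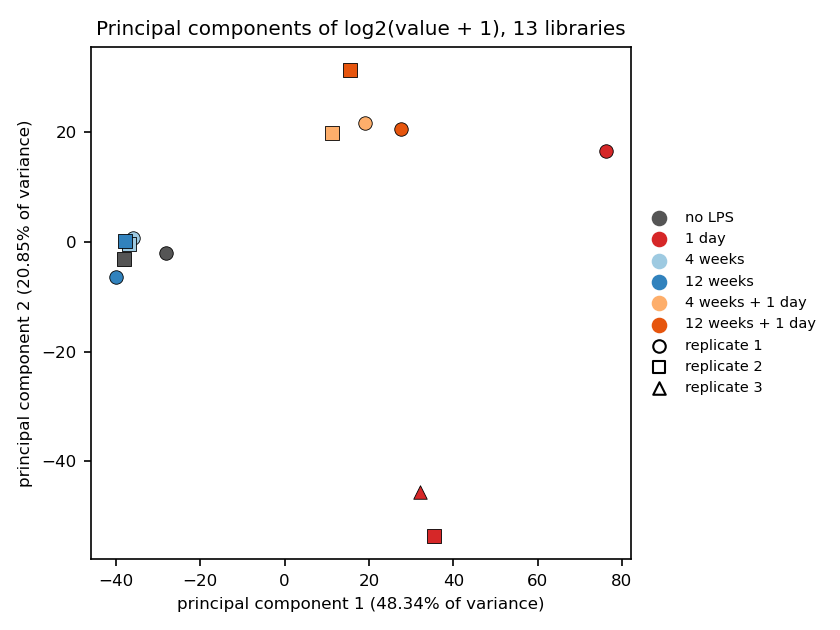
Principal components of log2(value + 1) over the 13 libraries, with the share of variance of each component in percent on its axis, groups as colours and replicates as symbols. The first component separates the libraries taken 1 day after LPS from the rest, and the second separates replicates 2 and 3 of the first response from replicate 1.

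**Figure D2:**
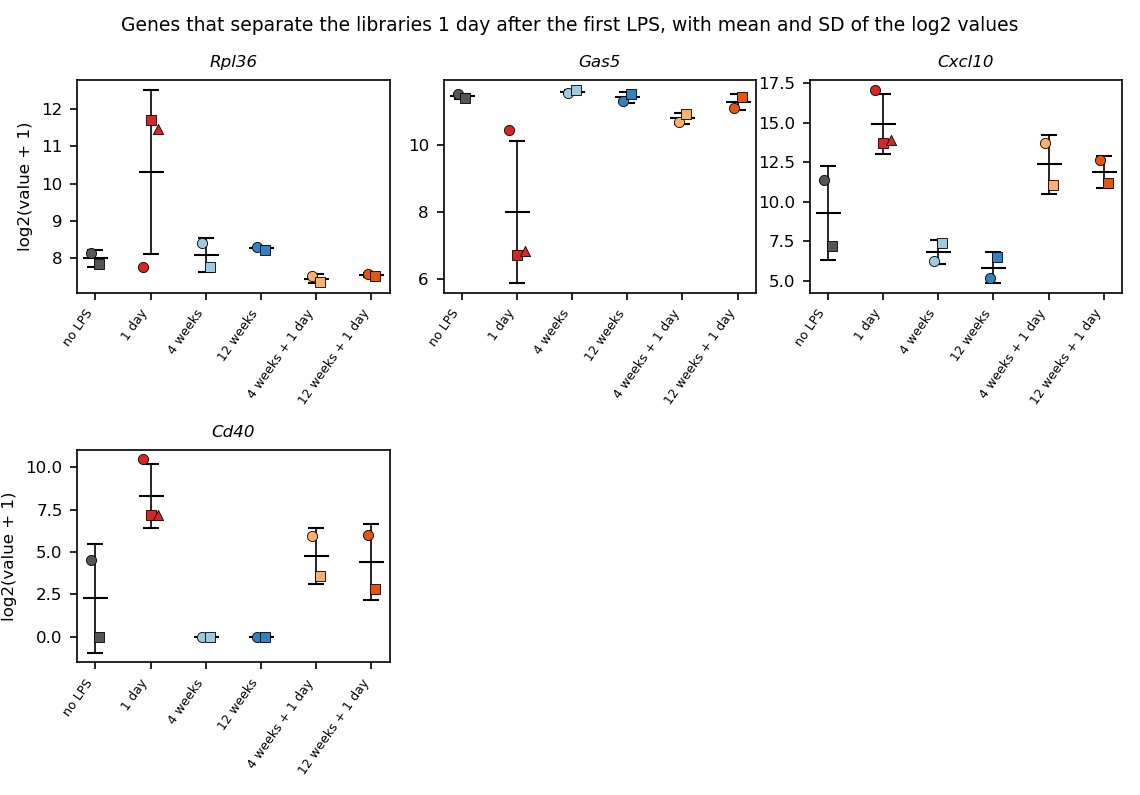
Per-library log2(value + 1) of 4 genes by group, with symbols for replicates and bars for mean and SD of the log2 values. Rpl36 is high and Gas5 low in replicates 2 and 3 of the first response, while Cxcl10 and Cd40 are highest in its replicate 1.

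The comparison of 1 day after a first LPS injection with no LPS asked which genes respond to a first challenge. Interferon-induced genes rose together: 43 of the 45 measured members of the interferon response list were higher, and 44 were when adjusted over the list alone. Irf7, a transcription factor that amplifies interferon signalling, went from 1043 ± 460 (n = 2) to 15090 ± 5570 (n = 3), a log2 change of 3.87 (SE 0.31, adjusted p = 2.9e-05). Isg15, a ubiquitin-like modifier, went from 701 ± 314 to 4803 ± 279. The list test had an adjusted p of 6.9e-48 with a preset and an adjusted p = 0.056 with an estimated correlation. Of the C/EBP and STAT3 acute-phase genes 13 of 23 rose, 14 when adjusted over the list alone, and this list kept its call (adjusted p = 0.017 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, went from 94.3 ± 31.8 to 1408 ± 184 (log2 change 3.92, adjusted p = 2.9e-05). Il1rn, the interleukin-1 receptor antagonist, had no read without LPS and was at 271 ± 172 after it, at least 27.2-fold higher, against a floor of 3 reads over the group. Cebpb, a transcription factor of emergency myelopoiesis, rose from 249 ± 45.5 to 1051 ± 211 (adjusted p = 0.00092) and its relative Cebpd from 102 ± 59.9 to 950.4 ± 249 (adjusted p = 9e-04). Among NF-kB targets 11 of 34 rose, 12 when adjusted over the list alone, such as the NF-kB inhibitor gene Nfkbia, from 1706 ± 254 to 5793 ± 2630 (list adjusted p = 0.12 with an estimated correlation). With replicate 1 of the first response alone 22 NF-kB targets rose and the list median went from 1.05 to 2.07, and without it 12 rose with a median of 0.96. The interferon list had 41 members risen without that replicate and 43 with it alone.

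Genes of antigen presentation moved with them. For MHC class I 11 of 21 genes rose, 12 when adjusted over the list alone (adjusted p = 0.021 with an estimated correlation). The peptide-loading gene Tapbp rose from 1943 ± 18.8 to 9689 ± 1080, and the immunoproteasome gene Psmb10, from 2427 ± 123 to 7039 ± 713. For MHC class II 5 of 10 rose and 1 fell, over the list alone as well (adjusted p = 0.067 with an estimated correlation). H2-Ab1, a class II chain, went from 665 ± 161 to 7265 ± 1940 and Cd74, the invariant chain, from 726 ± 468 to 6482 ± 819. The largest rises outside near-zero baselines included Cxcl9, a chemokine, from 298 ± 396 to 16600 ± 16000, and Ccl5, another chemokine, from 1472 ± 1840 to 63030 ± 26600. Pdcd1, which encodes the PD-1 receptor, had no read without LPS and was at least 31.5-fold higher at 296 ± 113. Ly6c1 had 2 reads without LPS and a read ratio of 145 (95% interval 40 to 1200), and the complement gene Cfb, also with 2 reads, had a ratio of 151 (41.7 to 1250). Cxcl9 lost its call with replicate 1 alone (adjusted p = 0.05).

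LT-HSC identity genes went the other way: 17 of 30 fell and none rose, and 19 fell when adjusted over the list alone, with a list median of −0.67 relative to that of all genes (adjusted p = 0.067 with an estimated correlation). Hlf, a transcription factor of stem cell quiescence, fell from 6667 ± 324 to 902 ± 449 (log2 change −3.04, adjusted p = 0.00024), Mllt3, a regulator of stem cell maintenance, from 1915 ± 84.6 to 463 ± 85.9, and the cell-cycle inhibitor gene Cdkn1c from 556 ± 134 to 49.1 ± 16.8. With median-of-ratios scaling 10 of these 30 genes still fell. Of 23 cholesterol synthesis genes 8 fell, 13 when adjusted over the list alone, such as Dhcr7 from 360.3 ± 112 to 84.3 ± 38.3 (list adjusted p = 0.22 with an estimated correlation), and 3 fell with the other scaling. The largest falls were those of Kazald1, from 411 ± 39.9 to 20.3 ± 3.42, Myl10, from 3586 ± 1230 to 183 ± 31.1, and Abcg3, from 525 ± 19 to 37.8 ± 16. Of the genes that set the gate, Ly6a, which encodes Sca-1, rose from 2151 ± 774 to 19140 ± 4560 and Kit fell from 4863 ± 239 to 1879 ± 441. Slamf1, which encodes CD150, was at 321 ± 73.1 and 169 ± 37.7 (adjusted p = 0.044), a call that ended with median-of-ratios scaling (adjusted p = 0.2). Counts over the 5 gate genes were 1 higher and 2 lower, and 1 higher and 3 lower when adjusted over the list alone. Whether the gate held the same kinds of cells with and without LPS was not tested. Differences 1 day after LPS, here and in the comparisons below, may therefore hold a change in which cells fell in the gate.

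Several lineage lists held members that moved in both directions. Myeloid progenitor genes had 6 of 20 risen and 1 fallen, also over the list alone (adjusted p = 0.067 with an estimated correlation). The cytokine receptor gene Csf2rb rose from 511 ± 198 to 5104 ± 1370 and Spi1, which encodes the myeloid factor PU.1, from 1098 ± 115 to 2224 ± 347. Megakaryocyte and platelet genes had 7 of 20 risen and 3 fallen, also over the list alone (adjusted p = 0.41 with an estimated correlation). Selp, which encodes P-selectin, rose from 224 ± 45.5 to 2107 ± 38.5, and Mmrn1, which encodes a platelet granule protein, fell from 1362 ± 180 to 333 ± 35.2. The platelet list median of 0.31 turned to −0.37 with replicate 1 of the first response alone (6 higher, 8 lower). HSC ageing-associated genes had 7 of 25 risen and 4 fallen, 10 and 6 when adjusted over the list alone (adjusted p = 0.09 with an estimated correlation), with Nupr1 from 180 ± 33.7 to 1214 ± 255. Multipotent progenitor genes had 3 of 15 risen and 1 fallen, 5 and 1 over the list alone (adjusted p = 0.082 with an estimated correlation), among them Cd53, a tetraspanin, from 60.9 ± 15.4 to 629 ± 190. Of the T and NK cell markers 2 of 6 rose (adjusted p = 0.067 with an estimated correlation), Ccl5 and the granzyme gene Gzmb, which had no read without LPS. Of 24 immediate-early genes 2 rose, 1 over the list alone (adjusted p = 0.19 with an estimated correlation). The remaining lists did not pass the preset test (adjusted p from 0.071 to 0.92). Among them 8 of 30 chromatin modifier genes fell, also over the list alone, such as Ezh2, the methyltransferase of Polycomb complex PRC2, from 810.2 ± 105 to 335 ± 44.4, and 3 fell with median-of-ratios scaling. Axl, a receptor listed with the macrophage markers, rose from 257 ± 1.02 to 809 ± 146 and Apoe fell from 10500 ± 518 to 4146 ± 1280. The macrophage list median of −0.75 was −1.42 without replicate 1 of the first response and 0.16 with it alone.

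In all, limma called 2300 of 15060 genes at an adjusted p under 0.05, 583 higher and 1717 lower, so that 74.7% were lower. The median of all genes was −0.34 on the log2 scale, and list medians are given relative to such shifts. With median-of-ratios scaling the calls were 953 higher and 699 lower (42.3% lower), and with trends on GC content and transcript length removed they were 1088 and 855 (44% lower). Both settings bring the median of all genes to about 0 by construction. The count was 614 without replicate 1 and 437 without replicate 2 of the group without LPS, 4601 without replicate 1 of the treated group, and 126 when only these 5 libraries were fitted, 87 higher and 39 lower (31% lower). Of the called genes 444 higher and 1399 lower were called with replicate 1 alone as well as without it.

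**Figure D3:**
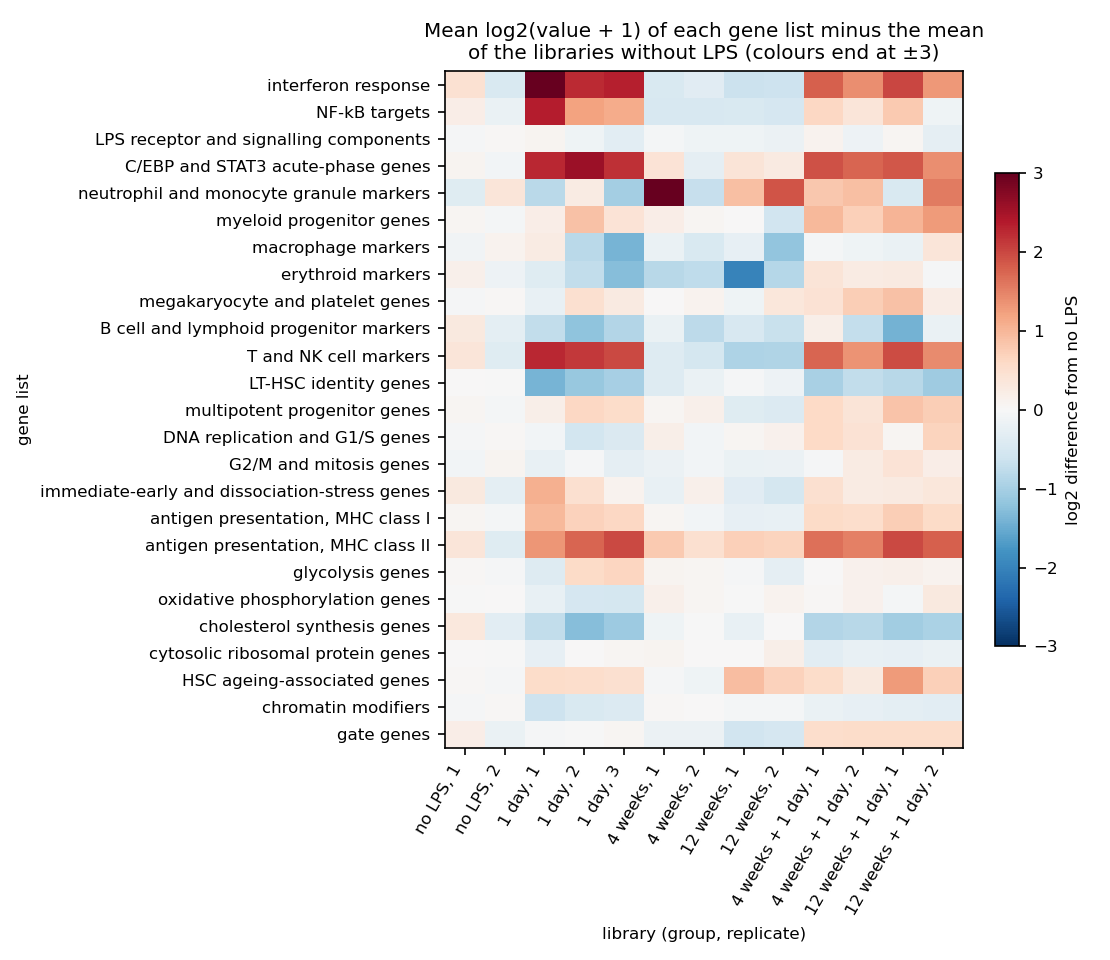
Mean log2(value + 1) of each of the 25 gene lists in each library minus the mean of the libraries without LPS, as colours that end at ±3, with libraries by group and replicate on the horizontal axis and lists on the vertical axis. The interferon, acute-phase and MHC lists are higher in the libraries taken 1 day after LPS and the LT-HSC identity list is lower, while single libraries carry the extremes of the granule list.

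The comparisons of 4 weeks and 12 weeks after LPS with no LPS asked what remained of the response. At 12 weeks Selp was higher, at 982 ± 78.5 (n = 2) against 224 ± 45.5 (n = 2), a log2 change of 2.14 (SE 0.25, adjusted p = 0.014), and it was the single gene called. HSC ageing-associated genes rose as a list, with a median of 0.67 relative to all genes and 8 of 25 members higher when adjusted over the list alone against 1 over all genes (adjusted p = 0.017 with an estimated correlation). Erythroid markers fell as a list, with a median of −1.64 and 2 of 18 lower over the list alone (adjusted p = 0.017 with an estimated correlation), with values such as 79.3 ± 47.4 against 277 ± 14.3 for the globin gene Hba-a1. The fall was larger in replicate 1 at 12 weeks, with a list mean of 6.046 on the log2 scale. It was 7.198 in replicate 2 and 8.205 and 7.889 without LPS. MHC class II genes rose as a list at both times (adjusted p = 1.9e-05 and 1.4e-05), a call that ended with an estimated correlation (adjusted p = 0.44 and 0.16). H2-Ab1 was at 1438 ± 358 at 4 weeks and 1403 ± 38.1 at 12 weeks against 665 ± 161, each with an adjusted p of 1. Over the list alone 1 class II gene was higher at 4 weeks and 2 were at 12 weeks.

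The interferon response list was lower at both times than without LPS, with medians of −0.28 and −0.38 relative to all genes (adjusted p = 0.74 and 0.32 with an estimated correlation). Its medians as measured were 0.01 and −0.1 without replicate 1 of the group without LPS, and −0.64 and −0.87 without replicate 2 of that group. Irf7 was at 579 ± 47.5 and 457 ± 32.7 against 1043 ± 460. NF-kB targets were lower as a list at both times (adjusted p = 0.74 and 0.47 with an estimated correlation). Neutrophil and monocyte granule markers were higher as a list (adjusted p = 0.74 and 0.36 with an estimated correlation). At 4 weeks replicate 1 carried this, with a list mean of 7.636 on the log2 scale against 3.814 in replicate 2 and 4.135 and 4.857 without LPS. Among them was Camp, an antimicrobial peptide of neutrophils, at 567 ± 755 and 280 ± 274 against 17.7 ± 17.2. At 4 weeks erythroid markers and LT-HSC identity genes were also lower and oxidative phosphorylation genes higher (adjusted p = 0.44, 0.74 and 0.74 with an estimated correlation). At 12 weeks macrophage markers and the gate genes were also lower and megakaryocyte and cytosolic ribosomal protein genes higher (adjusted p = 0.23, 0.15, 0.47 and 0.44 with an estimated correlation).

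At 4 weeks limma called 0 of 15060 genes, with 386 at an unadjusted p under 0.05 and 0 by limma-voom. At 12 weeks it called 1, with 412 unadjusted and 0 by limma-voom. Selp was not called without replicate 1 of the group without LPS or without either replicate at 12 weeks, each of which gave 0 genes, and without replicate 2 of the group without LPS the single call was a lower Ccl5. The 7 lists called at 4 weeks became 1 without replicate 1 of the group without LPS and 0 without replicate 1 at 4 weeks, and the 10 at 12 weeks became 6 without replicate 1 of the group without LPS or replicate 2 at 12 weeks. With the 3 libraries taken 1 day after the first LPS left out of the fit, a choice made after the data were seen, Selp (log2 change 1.3) and H2-Ab1 were among the genes higher at 4 weeks. At 12 weeks Selp, Aldh1a1, Nupr1 and H2-Ab1 were then higher and Plac8, Ebi3 and the globin genes Hbb-bt and Hbb-b2 lower.

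**Figure D4:**
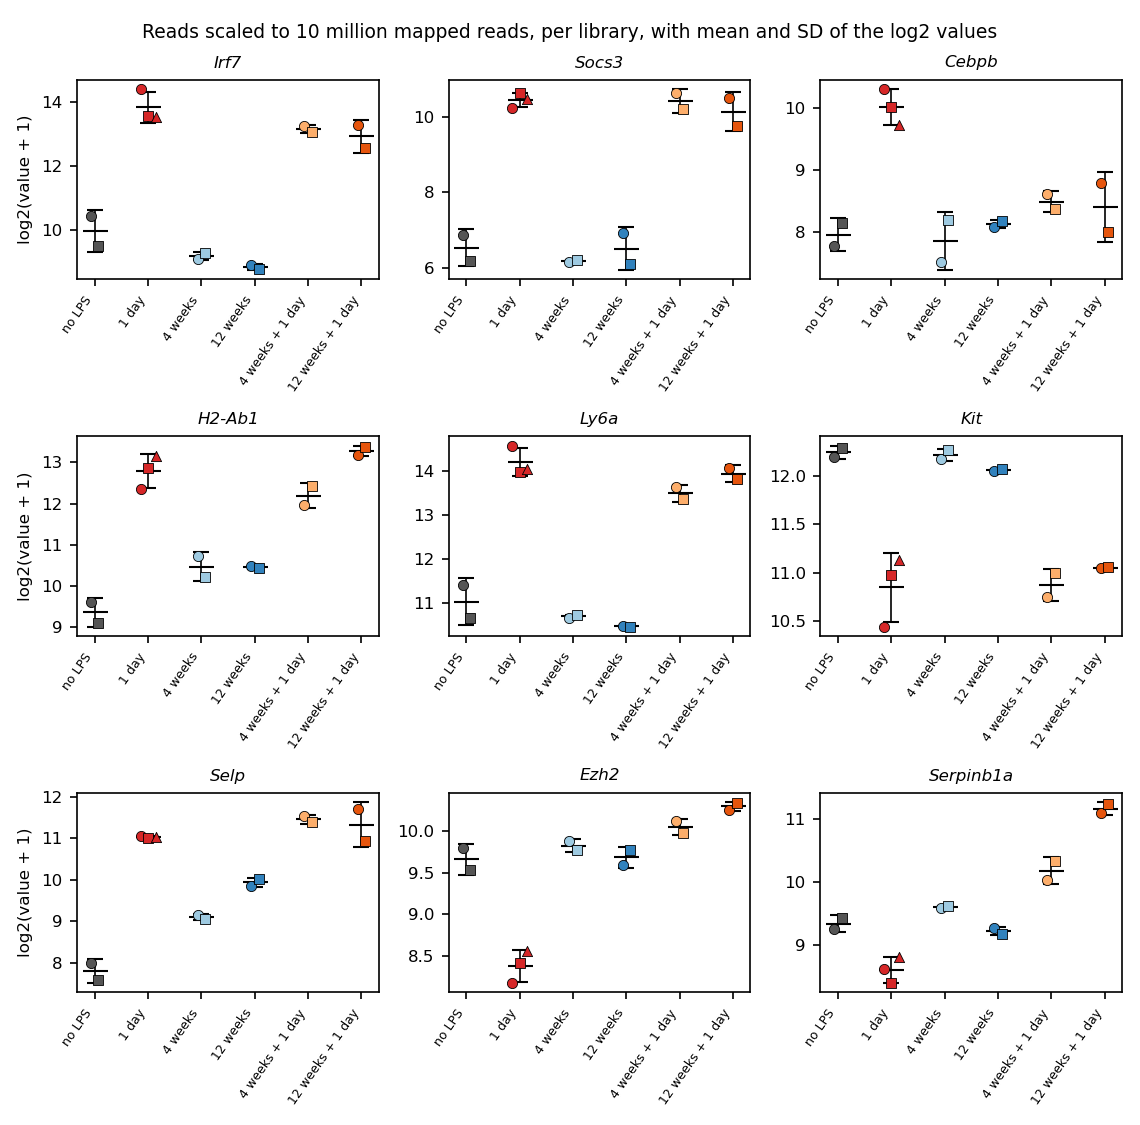
Per-library log2(value + 1) of 9 genes by group, where the value is reads per 10000000 mapped reads, with symbols for replicates and bars for mean and SD of the log2 values. Irf7, Socs3 and Ly6a are high in each library taken 1 day after LPS, Selp is higher at 4 and 12 weeks than without LPS, and Cebpb is highest after the first LPS.

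The comparison of a second challenge after 4 weeks with its own baseline asked how previously exposed cells respond. Interferon response genes rose again: 25 of 45 were higher, and 40 were when adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). Irf7 went from 579 ± 47.5 (n = 2) to 9063 ± 750 (n = 2), a log2 change of 3.97 (SE 0.34, adjusted p = 0.00017), and Bst2, the antiviral protein tetherin, from 1583 ± 3.27 to 6070 ± 165. Of the C/EBP and STAT3 acute-phase genes 5 of 23 rose, 9 over the list alone (adjusted p = 0.078 with an estimated correlation), among them Socs3 from 71.6 ± 1.25 to 1393 ± 300 and Saa3, an acute-phase protein, which had no read at 4 weeks and was at least 28.4-fold higher. Cebpb was at 359 ± 41.9 against 236 ± 76.4 and was not called (adjusted p = 0.33), while Cebpd rose from 81.9 ± 41.3 to 505 ± 54.1. NF-kB targets had 2 of 34 risen, also over the list alone (adjusted p = 0.48 with an estimated correlation). MHC class I had 5 of 21 risen, 10 over the list alone (adjusted p = 0.12 with an estimated correlation), and MHC class II 3 of 10 risen, 5 over the list alone (adjusted p = 0.15 with an estimated correlation), with Cd74 from 801 ± 202 to 5567 ± 842.

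LT-HSC identity genes fell, 3 of 30 over all genes and 11 over the list alone (adjusted p = 0.15 with an estimated correlation), with Hlf from 6016 ± 255 to 1617 ± 114 and Mllt3 from 1467 ± 383 to 730 ± 16.7. Myeloid progenitor genes had 2 of 20 risen (adjusted p = 0.15 with an estimated correlation), among them Plac8 from 1443 ± 1.11 to 8328 ± 209. Megakaryocyte genes had 6 of 20 risen and 1 fallen, 8 and 2 over the list alone (adjusted p = 0.25 with an estimated correlation), among them Itga2b, the platelet integrin chain, from 1204 ± 45.7 to 5076 ± 699. DNA replication genes were higher as a list, with a median of 0.51 relative to all genes and no member called (adjusted p = 0.32 with an estimated correlation). Counts of this kind depend on replicate 1 of the first response through the common variance: without it 11 DNA replication genes were higher, 12 LT-HSC identity genes lower and 7 NF-kB targets higher. Cytosolic ribosomal protein genes had 7 of 45 fallen and 1 risen, 10 and 2 over the list alone (adjusted p = 0.25 with an estimated correlation), such as Rps18 from 17580 ± 84.9 to 8722 ± 439. Ageing-associated genes had 6 of 25 risen, 7 and 1 fallen over the list alone, and cholesterol synthesis genes 1 of 23 fallen (adjusted p = 0.15 for each with an estimated correlation). The erythroid and T and NK cell lists were higher with 2 of 18 and 1 of 6 members risen (adjusted p = 0.15 for each with an estimated correlation), and the mitosis list with none (adjusted p = 0.35 with an estimated correlation). Ly6a rose from 1650 ± 41.6 to 11530 ± 1520 and Kit fell from 4781 ± 214 to 1882 ± 221. The largest rises with reads at baseline were those of Ccl5, from 118 ± 66.4 to 21310 ± 6000, and of Cxcl9, and the largest falls those of Myl10, from 2967 ± 601 to 254 ± 149, and Tle2. The test called 488 genes, 286 higher and 202 lower, and 82, 53, 65 or 89 without replicate 1 or 2 at 4 weeks or replicate 1 or 2 of the second challenge. With the first-response libraries left out of the fit it called 2647.

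After 12 weeks the second challenge raised 29 of 45 interferon response genes, 42 when adjusted over the list alone (adjusted p = 0.067 with an estimated correlation). Irf7 went from 457 ± 32.7 (n = 2) to 7952 ± 2750 (n = 2), a log2 change of 4.07 (SE 0.34, adjusted p = 7.2e-05), and Isg15 from 406 ± 40.2 to 2175 ± 308. MHC class I genes had 7 of 21 risen, 16 over the list alone (adjusted p = 0.037 with an estimated correlation), and MHC class II genes 4 of 10, also over the list alone (adjusted p = 0.089 with an estimated correlation), with H2-Ab1 from 1403 ± 38.1 to 9962 ± 889. Myeloid progenitor genes had 4 of 20 risen, 5 over the list alone (adjusted p = 0.037 with an estimated correlation), with Plac8 from 608 ± 70.3 to 10460 ± 679, a log2 change of 4.11. Multipotent progenitor genes had 4 of 15 risen, 7 over the list alone (adjusted p = 0.037 with an estimated correlation), among them Tespa1, which had no read at 12 weeks and was at least 14.7-fold higher. Erythroid markers had 2 of 18 risen, 8 over the list alone (adjusted p = 0.037 with an estimated correlation), such as Hbb-bt, whose reads may be shared with its near copy Hbb-b2, from 590.4 ± 18.2 to 3611 ± 239. The baseline libraries of this list were apart, at means of 6.046 and 7.198 on the log2 scale, against 8.311 and 8.012 after the challenge. Acute-phase genes had 5 of 23 risen, 7 over the list alone (adjusted p = 0.067 with an estimated correlation), with Socs3 from 93.9 ± 37.1 to 1168 ± 418, and NF-kB targets 1 of 34 (adjusted p = 0.5 with an estimated correlation).

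LT-HSC identity genes fell in 5 of 30 cases, 15 over the list alone (adjusted p = 0.067 with an estimated correlation), with Hlf from 5904 ± 214 to 1307 ± 225. G2/M genes had 2 of 27 risen, 4 over the list alone (adjusted p = 0.089 with an estimated correlation), the mitotic cyclin genes Ccnb2, from 834 ± 72 to 1746 ± 173, and Ccnb1, from 190.1 ± 18.2 to 510.1 ± 147. Cholesterol synthesis genes had 3 of 23 fallen, 6 over the list alone (adjusted p = 0.14 with an estimated correlation). Of the chromatin modifiers 2 of 30 fell, with Kmt2a, a histone methyltransferase, from 3057 ± 77.9 to 1410 ± 2.87, but the list did not pass. Without replicate 1 of the first response in the fit 19 LT-HSC identity genes were lower, and 8 DNA replication genes and 7 NF-kB targets higher. The platelet, ageing, ribosomal, macrophage, DNA replication, T and NK cell, immediate-early and gate lists also passed the preset test and none of them with an estimated correlation (adjusted p from 0.078 to 0.49). Selp rose from 982 ± 78.5 to 2669 ± 990, Ly6a rose from 1414 ± 14.1 to 15750 ± 2040 and Kit fell from 4278 ± 41.6 to 2119 ± 10.7. Cfb had no read at 12 weeks and was at least 68.8-fold higher at 563 ± 187, and Unc45b, a myosin chaperone gene, fell from 335 ± 27.4 to 25.3 ± 18.6. The test called 673 genes, 312 higher and 361 lower. It called 86 or 107 without replicate 1 or 2 at 12 weeks, 306 or 262 without replicate 1 or 2 of the second challenge, and 3172 with the first-response libraries left out of the fit.

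The responses to the first and second challenge resembled each other across 8963 expressed genes. The log2 changes of the first response correlated with those of the second at 0.66 after 4 weeks and 0.65 after 12 weeks, with no library in common and simulated values of −0.01 and 0. Those simulated values are near 0 by construction, since the simulated libraries vary independently. They cannot show whether a technical trend common to libraries adds to the likeness. Of the genes called in both, 161 were higher and 134 lower in both at 4 weeks (11.1 and 23 for independent lists), and 185 and 212 at 12 weeks (12.1 and 41.2), against 1 and 3 that went opposite ways. The second responses at 4 and 12 weeks correlated with each other at 0.85 and shared 191 risen and 112 fallen genes (5.93 and 4.84 for independent lists).

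The comparison of the second challenge after 4 weeks with the first asked how levels 1 day after LPS differed by history. The interferon, NF-kB and acute-phase lists had lower medians the second time, but did not pass with an estimated correlation (adjusted p = 0.35 for each) or with fry (0.077, 0.11 and 0.094). The interferon median as measured was −0.92, −0.62 without that replicate (13 lower, 1 higher) and −1.52 with it alone (28 lower). The NF-kB median was −0.99, −0.6 without it (7 lower, 1 higher) and −2.05 with it alone (18 lower). Of the interferon list 7 of 45 fell and none rose, and 17 fell over the list alone (median −1.16 relative to all genes, adjusted p = 0.35 with an estimated correlation). Isg15 fell from 4803 ± 279 (n = 3) to 1881 ± 33.8 (n = 2), a log2 change of −1.35 (SE 0.24, adjusted p = 0.0088), and the antiviral gene Mx2 from 718 ± 196 to 243 ± 1.83. NF-kB targets had 3 of 34 fallen, 4 over the list alone (adjusted p = 0.35 with an estimated correlation), among them the chemokine gene Ccl4 from 1141 ± 344 to 174 ± 36.1 and Nfkb2, an NF-kB subunit gene, from 901 ± 37.3 to 400.2 ± 68.7. Acute-phase genes had 3 of 23 fallen, 4 over the list alone (adjusted p = 0.35 with an estimated correlation). Cebpb fell from 1051 ± 211 to 359 ± 41.9 (log2 change −1.53, adjusted p = 0.011) and Stat3 from 3996 ± 553 to 2272 ± 144. Cebpd was at 505 ± 54.1 against 950.4 ± 249 and was not called (adjusted p = 0.27). Spi1 fell from 2224 ± 347 to 592 ± 25.7 and Axl from 809 ± 146 to 195 ± 34.7. DNA replication genes had 8 of 30 risen, 22 over the list alone (adjusted p = 0.43 with an estimated correlation), such as Rrm2, a ribonucleotide reductase subunit, from 167 ± 27.1 to 471 ± 17.5. Of the chromatin modifiers, whose list did not pass, 3 of 30 rose, with Ezh2 from 335 ± 44.4 to 1056 ± 71.8 and Hdac2, a histone deacetylase gene, from 389 ± 173 to 1149 ± 24.8. Cd34, listed with the multipotent progenitor genes, rose from 2066 ± 440 to 4630 ± 278 and Cd48, whose protein the gate excludes, from 33.2 ± 13.8 to 215 ± 14.7. MHC class I genes had 3 of 21 fallen and 1 risen, ribosomal protein genes 3 of 45 fallen and 1 risen, and oxidative phosphorylation genes 6 of 33 risen (adjusted p = 0.35, 0.35 and 0.6 with an estimated correlation). With median-of-ratios scaling 2 of the 30 DNA replication genes and 0 of the 33 oxidative phosphorylation genes were higher. Without replicate 1 of the first response 21 and 17 of them were higher and 0 and 4 lower, and with it alone 8 and 4 were higher.

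After 12 weeks the second challenge differed from the first in the same direction for these lists. Here too replicate 1 of the first response set the size: the interferon median of −0.91 was −0.49 without it and −1.25 with it alone, and the NF-kB median of −1.19 was −0.69 and −1.98. Of the interferon list 8 of 45 fell, 17 over the list alone (adjusted p = 0.48 with an estimated correlation), such as Isg15 to 2175 ± 308 (n = 2) from 4803 ± 279 (n = 3), and Socs1, a feedback inhibitor, to 273 ± 121 from 882 ± 199. NF-kB targets had 5 of 34 fallen, 8 over the list alone (adjusted p = 0.48 with an estimated correlation), with Nfkb2 at 228 ± 117 against 901 ± 37.3 and the chemokine gene Cxcl1 without a read against 38.5 ± 31.1. Acute-phase genes had 3 of 23 fallen, 4 over the list alone (adjusted p = 0.4 with an estimated correlation), with Cebpb at 349 ± 134 against 1051 ± 211 (log2 change −1.62, SE 0.3, adjusted p = 0.0095). Serpinb1a, a serine protease inhibitor, was at 2301 ± 165 against 390.1 ± 56 (log2 change 2.57, adjusted p = 9.2e-05) and Ezh2 at 1252 ± 45.6 against 335 ± 44.4. DNA replication genes had 5 of 30 risen, 14 over the list alone, G2/M genes 5 of 27, 6 over the list alone, and oxidative phosphorylation genes 7 of 33, 15 over the list alone (adjusted p = 0.48 for each with an estimated correlation). With median-of-ratios scaling 2, 0 and 1 of these genes were higher, without replicate 1 of the first response 20, 13 and 18 (0, 1 and 4 lower), and with it alone 7, 9 and 5. Rfc4, a clamp loader subunit of DNA replication, was at 421 ± 125 against 116 ± 39.9. B2m, the light chain of MHC class I, rose to 44480 ± 12800 from 16180 ± 6720 while Tapbp fell to 3935 ± 630 from 9689 ± 1080, in a list with 2 of 21 members risen and 2 fallen (adjusted p = 0.48 with an estimated correlation). Cytosolic ribosomal protein genes had 2 of 45 risen and 2 fallen (adjusted p = 0.48 with an estimated correlation).

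Against the first response the test called 1080 genes at 4 weeks, 904 higher and 176 lower, and 1059 at 12 weeks, 849 higher and 210 lower, while the median of all genes was 0.24 and 0.21. With median-of-ratios scaling these became 226 higher and 305 lower, and 281 and 376. Ezh2, Cd34 and Rrm2 kept their rises at both times. Leaving out replicate 1 of the first response gave 4193 and 4333 genes. At 4 weeks leaving out replicate 2 of the first response gave 691 and either replicate of the second challenge 0. At 12 weeks leaving out replicate 2 of the first response gave 575, replicate 1 of the second challenge 611 and its replicate 2 gave 7, and fitting only the groups compared gave 0 at both times. Of the calls 773 higher and 115 lower at 4 weeks, and 700 and 135 at 12 weeks, were called with replicate 1 of the first response alone as well as without it. The comparisons share the first-response libraries: their log2 changes correlated at 0.9 against 0.4 simulated, and their covariance was 0.395 against 0.048. The simulation gave all groups the same spread per gene. Replicate 1 of the first response differed far more from its group (chi-square per degree of freedom 33.99 and 30.18), so the simulated values may be too low. They cannot show a likeness beyond that from the shared libraries.

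The interaction asked whether the second response, against its own baseline, differed from the first. At 4 weeks Mthfd1, an enzyme of folate metabolism, fell from 769 to 309 in the first response and rose from 637 ± 30.2 (n = 2) to 1381 ± 127 (n = 2) in the second. The difference was 2.41 (SE 0.34, adjusted p = 0.038), and the transcription factor gene Mycn differed by 1.77 (SE 0.24, adjusted p = 0.038). Lipg, an endothelial lipase gene outside the expression limit set for named genes and singled out after its values were seen, had no read without LPS and 36.1 to 68 in the first response, against 5 and 6.6 at 4 weeks and no read after the second challenge. At 12 weeks Serpinb1a was called, from 594 ± 26 to 2301 ± 165 in the second response (difference 2.69, SE 0.29, adjusted p = 0.0056). No other gene passed at either time. Cebpb differed by −1.43 at 4 weeks and −1.79 at 12 weeks (adjusted p = 0.22 and 0.16). As lists, interferon genes differed by −0.83 and −0.55 relative to all genes, NF-kB targets by −1 and −0.95 and acute-phase genes by −0.91 and −1.09, and the calls ended with an estimated correlation (adjusted p from 0.16 to 0.56). The sizes of the first 2 of these depend on replicate 1 of the first response. As measured, the interferon medians of −0.53 and −0.29 were −0.22 and −0.13 without it and −1.05 and −0.71 with it alone. The NF-kB medians of −0.7 at both times were −0.34 and −0.33 without it and −1.51 and −1.62 with it alone. The acute-phase medians moved less, from −0.6 and −0.83 to −0.41 and −0.78 without it and −0.81 and −0.89 with it alone. The libraries without LPS matter too. In their replicates 1 and 2 the interferon list had means of 9.407 and 8.493 on the log2 scale, and the NF-kB list 6.554 and 6.151. The higher replicate 1 makes the first response smaller, and so the interactions of these lists less negative, than replicate 2 does. The test called 3 genes at 4 weeks (1917 at an unadjusted p under 0.05, 0 by limma-voom) and 1 at 12 weeks (1903 unadjusted, 1 by limma-voom). With only the groups compared, or with trends on GC content and transcript length removed, it called 0 at 4 weeks and 0 at 12 weeks. Without replicate 1 of the first response it called 2131 and 2441, and leaving out any other library of the comparison gave 0 at 4 weeks. At 12 weeks it gave 1 without replicate 2 or 3 of the first response, 4 without replicate 1 of the second challenge and 0 without any other.

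The last comparisons set the intervals side by side. At 12 weeks against 4 weeks HSC ageing-associated genes rose as a list, with a median of 0.82, 22 of 25 members above 0 and 4 higher over the list alone (adjusted p = 0.028 with an estimated correlation). Clu, which encodes clusterin, was at 514 ± 114 (n = 2) against 138 ± 9.64 (n = 2), and Sult1a1, a sulfotransferase gene, at 1128 ± 87.6 against 364 ± 85.6. Neither passed over all genes (adjusted p = 0.78 and 1). Interferon, erythroid and multipotent progenitor genes were lower as lists (adjusted p = 0.86, 0.086 and 0.061 with an estimated correlation). Replicate 1 at 12 weeks carried the erythroid difference. Its list mean was 6.046 on the log2 scale, against 7.198 in replicate 2 and 7.214 and 7.296 at 4 weeks. After the second challenge the ageing list was again higher at 12 weeks, with a median of 0.54, and the G2/M list was with 0.25 (adjusted p = 0.34 and 0.68 with an estimated correlation). Nupr1 was at 1726 ± 539 against 929 ± 93.2 and Mki67, a proliferation marker, at 668 ± 15.3 against 475 ± 11.8. Both comparisons called 0 genes by limma and by limma-voom, with 369 and 525 at an unadjusted p under 0.05. Without replicate 1 at 4 weeks Serping1 was called at 12 against 4 weeks and 7 lists passed instead of 4. After the second challenge Chic1 was called without replicate 1 at 12 weeks and Fam101b without its replicate 2, and the 2 lists called became 1 without replicate 1 of either group and 10 without replicate 2 at 12 weeks.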

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

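Of the tests below, those of sequencing depth, scaling, GC content, platelet transcripts and the biosynthesis lists had bounds written before their results, and those of the control library, carry-over and the first-response replicates had bounds written after the patterns were seen. The biosynthesis lists themselves were chosen after the leading genes were seen, so their bounds do not make them an independent test.

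In the first response 74.7% of the called genes were lower and the median of all genes was −0.34. Thinning to equal depth left a median of −0.32 over expressed genes, which met the bound against sequencing depth as the source. The median was −0.32 without thinning as well. The thinned reads were scaled back to the same total, so this median could hardly move. The test therefore cannot decide whether depth plays a part. Scaling by total reads stays open: with median-of-ratios scaling 42.3% were lower, which met the bound written for this explanation, but that scaling sets the median shift to 0 by construction, leaving the 100 highest genes out of the totals left −0.25, and the open verdict was adopted after these results were seen. GC content and transcript length were also left open after the result was seen: 84.8% of the main count was called after trend removal, which met the bound against this explanation, but that bound counted calls and not falls. The removal also centres each library and so cannot test the excess of falls, and while each of 5 bins of genes by GC content (−0.45 to −0.24) or length (−0.41 to −0.25) was lower over the group, the shift ran with GC in opposite directions, from 0 to −0.82 in replicate 1 and from −0.71 to −0.12 in replicate 2.

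At 4 and 12 weeks the interferon list lay below the group without LPS. This could come from 1 control library: without its replicate 1 the median difference was −0.05 over both times, and 44 of 45 members were higher in that replicate than in the other. Carry-over of reads from first-response libraries into that replicate was left open at a median level of 1.7% over 13 genes, between the bounds, but this is short of the 5.2% that the list would need and the other control was at 0.91%. These genes were chosen as high after LPS, and Gbp6 of the interferon list is among them. A true rise of such genes in that control would look the same, so the test cannot tell it from carry-over. Age could also matter, but the age of the mice without LPS at harvest is not given in the sources used here.

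Replicate 1 of the first response lay beyond all other libraries in 140 genes above and 618 below, and replicates 2 and 3 together did in 57 and 121. These counts are not alike, since a pair passes only where both of its libraries do. Replicate 1 held 1250677 reads in genes, within the range of 1096465 to 1773615 in the other groups, while replicates 2 and 3 held more, at 2308087 and 2088789. The sources weighed here are those of the distance between replicate 1 and replicates 2 and 3. GC content and length are not a likely sole source, as the correlation after trend removal was 0.824, and neither is a wrong label within the series alone: the highest correlation was 0.86, with a second-challenge library at 12 weeks, more than the 0.774 and 0.785 with its own group but less than the 0.9436 to 0.9697 within other groups. Another library preparation or read counting in replicates 2 and 3 is consistent with an SD over the ribosomal protein list of 1.28 and 1.31, just past 2 times the highest of the other groups (0.629), against 0.661 in replicate 1, but it does not account for the genes in which replicate 1 departs from all others. RNA from other cell types stays open, although the sort should remove such cells. The highest list median was 1.82, that of macrophage markers (12 of 16 above 0). It came more from low values in replicates 2 and 3 than from a rise in replicate 1. The macrophage list means on the log2 scale were 6.655 in replicate 1, 5.589 and 5.011 in replicates 2 and 3, and 6.289 and 6.52 without LPS. Another strength of the response stays open as well (r = 0.31). RNA quality and a sample from outside the series were not tested, nor which of the 2 kinds is the usual one.

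The other results singled out are given as values. In the interaction at 4 weeks Lipg differed by −8.44 on few reads (−4.58 with a pseudocount of 5), Mthfd1 by 2.41 and Mycn by 1.77. Relative to all genes the lists differed at 4 weeks by −0.83 (interferon response), −1 (NF-kB targets), −0.91 (C/EBP and STAT3 acute-phase genes), 0.85 (erythroid markers), 0.45 (LT-HSC identity genes), 0.58 (DNA replication), −0.69 (MHC class I), −1.26 (MHC class II) and −0.6 (cytosolic ribosomal protein genes), with adjusted p from 0.37 to 0.51 with an estimated correlation. Replicate 1 of the first response moved these. As measured, the NF-kB median was −0.34 without it and −1.51 with it alone, and the MHC class II median −1.23 and −0.25. The first-response median of the ribosomal list was 0.06 without it and −0.26 with it alone. That list had its largest SDs in replicates 2 and 3 (1.28 and 1.31), so its differences at 4 and 12 weeks depend on these libraries. The interferon difference also depends on the control, with list means of 9.407 and 8.493 in replicates 1 and 2 without LPS. At 12 weeks Serpinb1a differed by 2.69. The lists differed there by −0.55 (interferon response), −0.95 (NF-kB targets), −1.09 (acute-phase genes), 1.35 (erythroid markers), 0.37 (DNA replication), 0.49 (G2/M), −0.47 (cytosolic ribosomal protein genes) and −0.55 (HSC ageing-associated genes), with adjusted p from 0.16 to 0.56 with an estimated correlation.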

How the results depend on the processing

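Every alternative below was rerun on the same libraries, and for differences between settings the cause was not tested. DESeq2, foreseen for counts, was not run because the values are normalized, and limma-voom on recovered reads took its place. Leaving out 1 library of the groups compared at a time gave 437 to 4601 genes for 1 day against no LPS, 0 to 0 for 4 weeks and 0 to 1 for 12 weeks against no LPS. It gave 53 to 89 and 86 to 306 for the second responses at 4 and 12 weeks and 0 to 4193 and 7 to 4333 for the second against the first challenge. It gave 0 to 2131 and 0 to 2441 for the interactions, and 0 to 1 for 12 against 4 weeks, without or with the second challenge. The called lists ranged over 12 to 16, 0 to 8, 6 to 13, 13 to 16, 13 to 18, 6 to 8, 6 to 9, 8 to 10, 8 to 11, 3 to 7 and 1 to 10 in the same order. Libraries of the other groups enter through the common variance, and leaving them out was added after the data were seen. Without replicate 1 of the first response the second responses had 2826 and 3400 genes, 4 and 12 weeks against no LPS 4 and 13, and 12 against 4 weeks 2 and 8 without and with the second challenge. The second response at 4 weeks had 276 or 276 genes without replicate 1 or 2 of no LPS and 271 or 273 without those of 12 weeks, and that at 12 weeks 448 or 448 without those of no LPS. The second against the first challenge at 4 weeks had 698 or 707 genes without replicate 1 or 2 of no LPS, 698 or 699 without those of 4 weeks and 693 or 694 without those of 12 weeks. At 12 weeks it had 636 or 636, 648 or 649 and 618 or 613, and 620 or 615 without those of the second challenge at 4 weeks. For 12 weeks against no LPS 0 genes were called without either library of 4 weeks or of its second challenge, and for the interaction at 4 weeks 0 without either library of 12 weeks or of its second challenge. With an estimated correlation the called lists were 2, 0, 2, 0, 4, 0, 0, 0, 0, 1 and 0. With fry they were 0 at 4 weeks and 4 at 12 weeks against no LPS, 3 for the second against the first challenge at 4 weeks, 0 and 4 for the interactions, and 2 and 0 for 12 against 4 weeks without and with the second challenge. Array weights gave 5809 genes for 1 day against no LPS, 5 and 14 for 4 and 12 weeks against no LPS, 2910 and 2445 for the second responses, 5021 and 3682 for the second against the first challenge, 2471 and 2114 for the interactions and 4 for 12 against 4 weeks. Replicate 1 of the first response alone gave 5205, 4015 and 3746 genes for the comparisons with the first response and 2638 and 2176 for the interactions. Fitting only the groups compared gave 126 genes for 1 day and 8 for 12 weeks against no LPS, 2775 and 1716 for the second responses, 0 and 0 against the first challenge, 0 and 0 for the interactions and 3 for 12 against 4 weeks. No library of the first response in the fit gave 4 and 8 genes for 4 and 12 weeks against no LPS, 2647 and 3172 for the second responses, and 2 and 3 for 12 against 4 weeks without and with the second challenge. Median-of-ratios scaling gave 531 and 657 genes for the second against the first challenge and 0 for the interaction at 4 weeks. Removing GC content and length trends gave 683 genes for the second against the first challenge at 12 weeks and 0 and 0 for the interactions. The interaction at 4 weeks also gave 0 genes with limma-voom, with a pseudocount of 0.1, with at least 5 CPM, with reads thinned to equal depth and with a replicate block. At 12 weeks against no LPS limma-voom gave 0 genes and a pseudocount of 0.1 gave 2. The replicate block gave 7 lists for 12 against 4 weeks, but whether replicate numbers pair libraries across groups stays open, as their deviations correlated at −0.15 to 0.19, with 5 of 15 pairs above 0.1. Over the genes called in the first response its correlation with the second was 0.77 at 4 weeks and 0.77 at 12 weeks. Of the values of named genes over these settings 3648 stayed the same, 615 were weaker, 30 stronger and 0 reversed.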

Other observations

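Biosynthesis genes outside the lists set beforehand were looked at after the results were seen, in lists chosen after the leading genes were known. Their p-values come from the same data and are not adjusted over lists or comparisons, so they are descriptions. Of 19 aminoacyl-tRNA synthetase genes, whose products charge transfer RNAs for translation, 5 rose in the second response at 4 weeks and 3 at 12 weeks (p = 0.015 and 0.035 with an estimated correlation). The list was higher in the first response as well, with 2 risen, 1 fallen and a median of 0.7 relative to all genes (p = 0.16 with an estimated correlation), against 0.66 and 0.54 in the second. In the interactions their p-values with a preset correlation were 0.0047 and 0.065, which leaves open whether the second response differs from the first. Of 26 ribosome biogenesis genes 8 at 4 weeks and 7 at 12 weeks were higher after the second challenge than after the first (p = 0.18 and 0.16 with an estimated correlation). In the interactions they differed by 0.36 and 0.39 relative to all genes (larger p = 8.5e-05 with a preset correlation, and p = 0.23 and 0.22 with an estimated one). Mitochondrial ribosomal protein genes did not pass limma in either interaction (larger p = 0.19 with a preset correlation). A quantitative translation assay of LT-HSCs after 1 or 2 challenges could test whether protein synthesis differs.

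The HSC ageing-associated list was higher at 12 than at 4 weeks, and more platelet-lineage transcripts are not a likely reason: without the 3 shared genes the medians were 0.84 for 22 ageing-associated genes and 0.03 for 17 platelet genes, a ratio of 0.04. The labelled age of 6 to 8 weeks cannot be that at harvest 12 weeks after LPS. If it is the age at the first injection, the mice were also older at 12 weeks. Untreated mice known to be of the same age would be needed to separate time from LPS.

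Xist, the RNA that silences 1 X chromosome in female cells, was at 3098 and 2986 without LPS, at 1040, 1042 and 1044 after the first challenge, and at 1868 to 2121 after the second. Of the Y-linked genes Ddx3y had 7 reads over all libraries and Kdm5d 0, so the pools carry next to no male RNA. The lower Xist level is thus not a change in the share of male mice, and its cause was not tested.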
